A study of Mus musculus with 10 samples.

How the data were processed

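RNA was sequenced from the cortex of mouse embryos at embryonic day 12, in 10 libraries of polyadenylated RNA prepared from RNeasy extracts, per the labels' protocols. Each library is labelled as 1 animal. The 5 libraries called WT carried the Emx1-Cre driver and 2 wild-type Zbtb7a alleles. The 5 libraries called cKO (conditional knockout) carried the driver and 2 floxed Zbtb7a alleles. Emx1-Cre is active in progenitors of the dorsal telencephalon, so the floxed allele is cut in cells of that lineage and stays intact in other cells of the tissue. The labels name the litter as the batch. Litter 1 gave WT 1, WT 2, cKO 1, cKO 2 and cKO 3, litter 3 gave WT 3, WT 4 and cKO 4, and litter 5 gave WT 5 and cKO 5. The series description counts 3 cortices per condition from 2 litters, which differs from the labels of the 10 libraries. The labels were followed here.

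The authors deposited TPM, transcript abundances scaled to a total of 1000000 per library, for 24814 genes in the 10 libraries, with 2 decimals. The authors also deposited a comparison of cKO with WT for 7 genes. Per the file headers and the file's values, this deposited table holds a fold change taken as log2, its standard error, a test score that the authors made as their ratio, and an adjusted p-value. The base of the fold change is not stated in the file and was taken as 2 because DESeq2 is named in the submitters' processing notes. Those notes also name cutadapt, featureCounts and the mouse build mm10, with no versions or roles. The aligner is not given in the sources used here. Nor are the tool behind the TPM values, the treatment of reads that align to several places, the use of strand, or the libraries and covariates behind the 7-gene table. TPM keeps no read depth, so the depth of each library is unknown, and no count model or counting interval was used. The number of genes above 0 TPM ranged from 18991 in cKO 2 to 19944 in cKO 4.

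Gene identifiers were matched to GENCODE M21 on GRCm38, which placed 24762 of the 24814. Spreadsheet dates stood in place of 26 gene symbols, which were restored from the identifiers. A further 5 columns of the TPM table have no library name and hold 4 values each. They were not used.

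Genes with a TPM of at least 1 in at least 5 libraries were tested, which left 13833. Values were transformed as log2(TPM + 1), and fold changes on this scale understate the change of genes with low TPM. The main test was limma 3.58.1 in R 4.3.3, with litter and genotype as terms, empirical Bayes moderation with a trend, 6 residual degrees of freedom and two-sided p-values. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Intervals of fold changes are at the 95% level. Gene lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 37 lists with at least 4 tested members. Camera with an estimated correlation and fry were the alternatives. A 38th list, of germline genes, had no tested member among its 17 genes. The interaction of genotype with litter 1 against the other litters was tested in limma as well. Single genes were also compared by two-sided exact permutation tests over all splits into 5 and 5. These used the mean log2(TPM + 1) for Zbtb7a, Tdg, Gm9855 and Fgf17, and the mean TPM for Zfp433 and for sums of copies. The within-litter tests took the genotype effect on log2(TPM + 1), fitted with litter, over the 60 arrangements that keep the litters. The smallest possible p-values are 0.00794 over all splits and 0.0167 within litters. The p-values measure the spread between animals of these 3 litters.

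The design, the gene lists and the rule for named genes were chosen before the data were examined. The rule takes Zbtb7a, then the called genes with the largest change in each direction and the same sign in every litter, up to 12. Where fewer than 10 are called, the list is filled to 10 by the smallest p-value, as values that did not pass. It also takes the 2 to 4 members with the smallest p-value of each list described, and every gene of the authors' deposited table. Zfp433, BC024063, Prtn3 and Zfr2 are outside the rule and were chosen after their values were seen, as copies or neighbours of named genes, and so were Gad2, Gm10240, Gm13370, Gm13841, Gm8210 and the leading genes of a regrouping of the libraries. Fgf8 was chosen after the values of Fgf17 were seen and before its own.

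The pipeline was tested on simulated data for the comparison of cKO with WT, with 13833 genes, 200 of them changed, in 20 draws. It called 43.6% of genes changed 1.5-fold, 69.5% of those changed 2-fold, 84.8% of those changed 3-fold and 91.5% of those changed 4-fold. No gene was called in draws with no change, and on average 4.83% of the calls were genes that had not been changed. Each gene was drawn independently of the others, so the simulated libraries lack correlation between genes. These rates may not hold for the real libraries. Near-identical copies of named genes were searched with blastn 2.17.0 against the GENCODE M21 transcripts. Permutation tests used scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

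The alternatives changed the pseudocount, the filter, the treatment of litter, the scaling, the moderation, the library weights and the set of libraries, and added Xist as a covariate. Leaving out litter 3 or litter 5 was added after seeing the data. A count test on recovered whole reads was planned for the case that the values allowed it, and was not run because TPM keeps no depth. The numbers of the animals in the labels do not mark a shared litter in every case, since WT 3 is from litter 3 and cKO 3 from litter 1, so they were not used as pairs in the main test.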

Results

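The cortex of 10 mouse embryos at embryonic day 12 was profiled by RNA sequencing, 5 with wild-type Zbtb7a (WT) and 5 in which Emx1-Cre acts on 2 floxed Zbtb7a alleles (cKO). The embryos came from 3 litters, each of which held both genotypes. Litter 1 gave 2 WT and 3 cKO libraries, litter 3 gave 2 WT and 1 cKO, and litter 5 gave 1 of each. Values are TPM as deposited by the authors, and the depth of the libraries is unknown. Pearson correlations between libraries over the tested genes were 0.949 to 0.984. The comparison asks which transcripts of the early cortex differ when Zbtb7a, which encodes a BTB zinc finger transcriptional repressor, is deleted from the dorsal telencephalic lineage.

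Zbtb7a itself (ENSMUSG00000035011, chromosome 10, 81135220 to 81152995 on GRCm38) was read first, as a check of the labels. Its TPM was 9.59 ± 2.32 in WT and 4.46 ± 1.02 in cKO (SD, n = 5 each), a ratio of 0.465. Every cKO library lay below every WT library, with an exact permutation p of 0.00794, the smallest that 5 against 5 allows. Within litters the exact permutation p was 0.0167, also the smallest possible. The log2 fold change was -0.99 (SE 0.19, 95% interval -1.40 to -0.57). Over all tested genes this did not pass (limma, Benjamini-Hochberg adjusted p = 0.615). The difference on the log2 scale was -1.29 within litter 1, -0.26 within litter 3 and -1.23 within litter 5. The only cKO library of litter 3, cKO 4, had 5.96 TPM, the highest of the cKO libraries, and without it the log2 fold change was -1.27 and the gene was called (limma, adjusted p = 0.0277). The gene-level value includes exons outside the deleted part and cells without Cre, so it does not measure how complete the deletion was.

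Of 13833 genes tested, 1 was called higher in cKO and 4 were called lower. Tdg, which encodes thymine DNA glycosylase, an enzyme of base excision repair that also takes part in active DNA demethylation, fell in cKO. The gene Tdg (chromosome 10, 82629828 to 82650799) had 226 ± 24.4 TPM in WT and 134 ± 9.72 in cKO (SD, n = 5), a log2 fold change of -0.78 (SE 0.07; limma adjusted p = 0.00183). Gm9855, a processed pseudogene of Tdg on the same chromosome (42054113 to 42055306), rose from 11.6 ± 2.37 to 124 ± 9.80 TPM, a log2 fold change of 3.30 (SE 0.13; limma adjusted p = 3.09e-06). Gm5597, another processed Tdg pseudogene (chromosome 7, 76244746 to 76245938), had 1.17 to 2.68 TPM in the WT libraries and was listed at 0 in all 5 cKO libraries (limma adjusted p = 0.0186). The other 2 called genes belong to a cluster of zinc finger genes on chromosome 10. Gm32687 (81863934 to 81881081) had 3.81 to 5.74 TPM in the WT libraries and was listed at 0 in all 5 cKO libraries (limma adjusted p = 8.42e-05). Gm3055 (81742821 to 81771161) fell from 11.6 ± 2.45 to 4.99 ± 0.402 TPM, a log2 fold change of -1.11 (SE 0.12; limma adjusted p = 0.0121). For each of these 5 genes the genotypes did not overlap, and the difference had the same sign in all 3 litters.

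**Figure D1:**
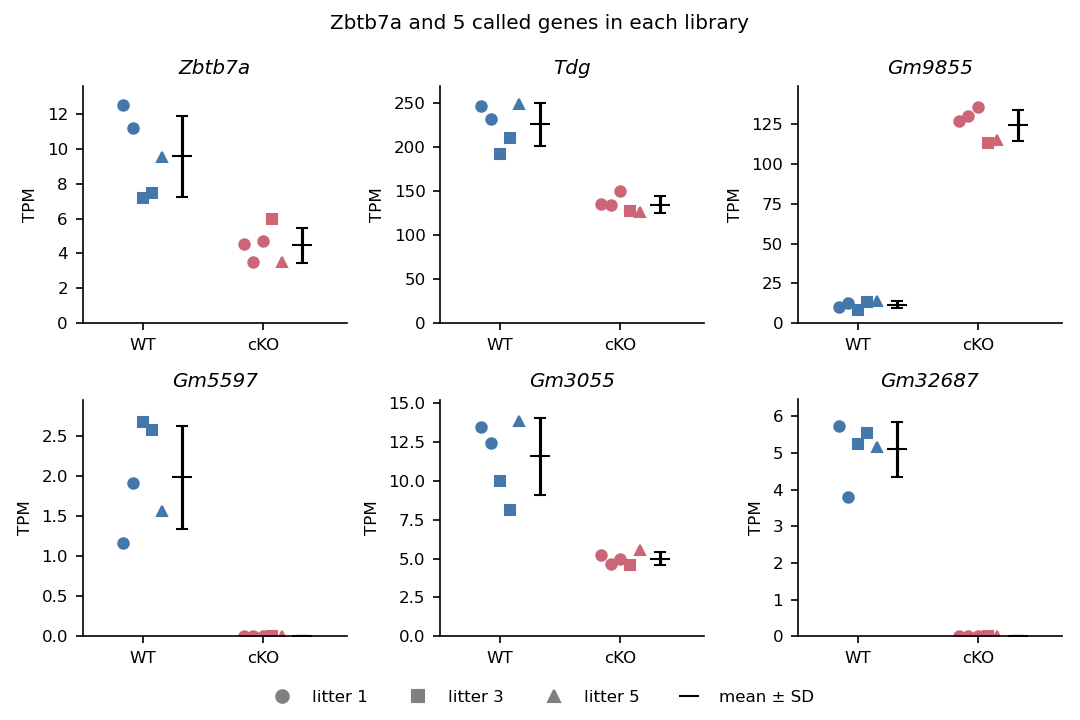
TPM of Zbtb7a and the 5 called genes in each library, with 1 panel per gene, WT in blue and cKO in red, the marker shape giving the litter and black bars the mean ± SD of 5 libraries. In every panel the genotypes are apart, and Gm9855 lies at 8.27 to 14.0 TPM in WT and 113 to 136 TPM in cKO.

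Each called gene has a near-identical copy in the genome, so its value is uncertain where reads of copies cannot be told apart. Over their aligned bases Gm9855 and Tdg are 99.2% identical (1194 bases) and Gm5597 and Tdg 99.3% (1193 bases). Gm32687 is 99.9% identical to Zfp433 over 2379 bases. Gm3055 is 99.9% identical to Zfp781 over 4067 bases and 98.9% identical to BC024063 over 2480 bases. Summed over Tdg and its copies Gm9855, Gm5597 and Gm5806, the TPM was 240 ± 25.1 in WT and 262 ± 19.1 in cKO (SD, n = 5; exact permutation p = 0.167). Weighted by transcript length, the sum was 231 ± 24.7 in WT and 179 ± 12.9 in cKO (exact permutation p = 0.0159). The value of Zfp433 was 6.58 ± 2.08 TPM in WT and 6.68 ± 0.898 in cKO, a difference smaller than the spread between libraries (exact permutation p = 0.937).

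Tdg, Gm3055 and Gm32687 all lie within 2 Mb of Zbtb7a. In this window 9 of 124 tested genes (7.26%), Zbtb7a left out, had an unadjusted limma p under 0.05, these 3 included, against 313 of 13695 genes elsewhere (2.29%). With the called genes left out the odds ratio was 2.24 (6 of 121 against 311 of 13693; Fisher's exact test p = 0.0601), and for window genes without a near-identical copy it was 1.57 (4 of 113; one-sided Fisher's exact test p = 0.261). The 6 genes besides the called 3 did not pass the adjustment. Zfp781 had 2.20 ± 0.492 TPM in WT and 4.20 ± 0.232 in cKO (log2 fold change 0.73). Gm4924 had 2.65 ± 0.216 and 4.50 ± 0.815 (0.62). Prtn3, Zfr2, BC024063 and the long noncoding RNA AC158605.1 had log2 fold changes of 0.70, -0.48, 0.52 and -1.02.

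**Figure D2:**
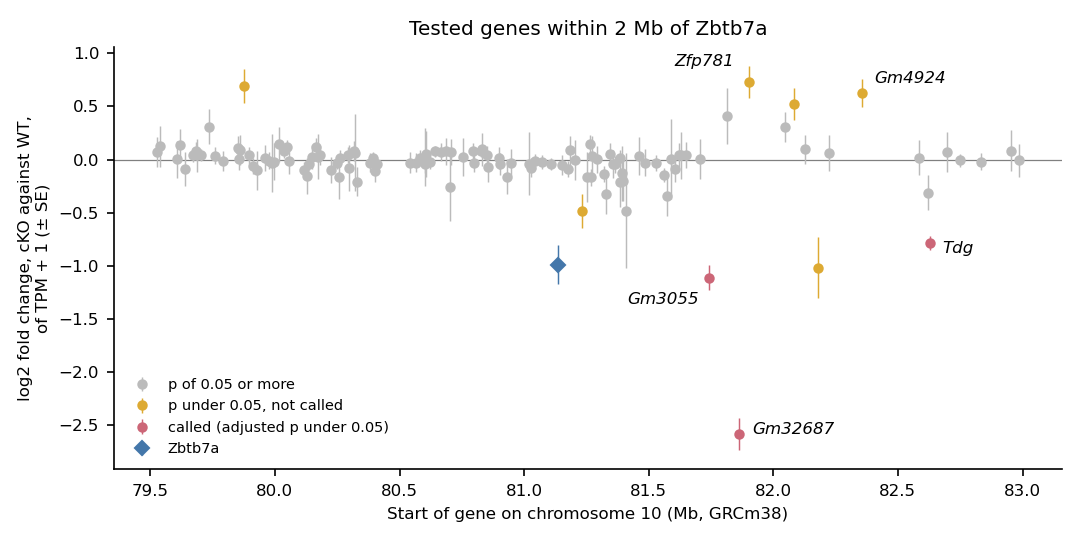
Log2 fold change of TPM + 1, cKO against WT, of each tested gene within 2 Mb of Zbtb7a, against the start of the gene on chromosome 10 in Mb, with bars of 1 SE. Colours mark Zbtb7a, the called genes and genes with an unadjusted p under 0.05, and Gm32687, listed at 0 in cKO, is the lowest point at -2.58, a value set by the pseudocount.

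Beyond these genes the profiles of the genotypes were close. The median log2 fold change was -0.01, and for 95.7% of tested genes the 95% interval on the log2(TPM + 1) scale excluded a change of more than 2-fold. An unadjusted p under 0.05 was found for 171 genes higher and 153 lower in cKO, or 2.34% of those tested. The genotypes did not overlap for 39 genes (0.282%), where chance gives 0.794%. The genes with the next smallest p-values did not pass (limma adjusted p of 0.615 or more) and are given as values. Higher in cKO in every litter were Xlr3b (log2 fold change 1.15), the antisense transcript RP23-448A11.8 at Rhoa (0.81), BC024139 (0.98), Rcbtb2 (0.26), the secreted factor gene C1qtnf4 (0.57), A230056P14Rik (1.34) and the Tdg pseudogene Gm5806 (0.79). Lower in every litter were the Rpl21 pseudogene Gm10163 (-4.30), 6720489N17Rik (-0.43), the mitochondrial magnesium channel gene Mrs2 (-0.44) and the myeloid receptor gene Treml2 (-0.67). The value of Gm10163 is uncertain, since 97 genes match over more than 50% of its transcript, and so are those of RP23-448A11.8, which shares 324 of 347 bases with Rhoa, of Xlr3b, which Xlr3a matches along the whole transcript (3785 aligned bases), and of 6720489N17Rik, which matches Gm7240 at 85.5% over 1507 bases.

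The main cell classes of the early cortex showed no called difference over the 10 libraries with a litter term. Among 15 apical progenitor markers the median log2 fold change was 0.01, with Hes1 at 0.11 and Fabp7 at 0.11. Of 15 markers of intermediate progenitors, the committed cells that express Eomes, 13 were lower in cKO with a median of -0.09, and Neurog2 was at -0.20 and Elavl4 at -0.15. Early cortical neuron markers had a median of -0.05 over 19 genes, with Zfpm2 at -0.41 and Slc17a6 at -0.24. Upper-layer factors had a median of 0.03, with Mef2c at -0.40 and Lmo4 at 0.20, and Cajal-Retzius markers 0.11, with Lhx5 at 0.47 and Reln at -0.37. The smallest adjusted p among these 5 lists was 0.0959 (camera). These lists did pass in some alternatives with the preset correlation. The directions of list calls in the alternatives, here and below, were not compared between settings. Such calls therefore lend no support to a shared direction. Early cortical neurons were called without WT 1, WT 2, WT 5, cKO 1, cKO 2 or cKO 5, without litter 5, in litter 1 only and in litters 3 and 5 only. Leaving out WT 5, cKO 5 or litter 5 gives the same genotype estimates, since the litter term fits a lone library exactly. They therefore count as a single alternative, here and below. Leaving out cKO 4 or litter 3 likewise gives the same genotype estimates. Intermediate progenitors were called without WT 2, WT 3, cKO 1 or cKO 2 and in litters 3 and 5 only. Upper-layer and Cajal-Retzius neurons were called without WT 5, cKO 5 or litter 5 and in litter 1 only, upper-layer neurons also in litters 3 and 5 only, and apical progenitors with a replicate block and no litter term. Proliferation genes were also close between the genotypes. The median was 0.00 for 23 DNA replication genes, with Slbp at -0.08 and Ccne2 at 0.11, and -0.04 for 23 mitosis genes, of which 21 were lower, with Aurkb at -0.10 and Hmmr at -0.10. Of the pathways that ZBTB7A is reported to act on, the Notch list had a median of -0.04, with Jag2 at 0.38 and Lfng at 0.19. The p53 target list had a median of -0.03, with Perp at 0.37 and Eda2r at -0.24. None of these 4 lists was called (camera adjusted p of 0.172 or more), but mitosis was called without WT 3, cKO 3, cKO 4 or litter 3, with Xist as a covariate and with a replicate block beside the litter term.

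Glycolysis genes, a pathway that ZBTB7A is reported to repress, were higher in cKO in 18 of 23 members with a median of 0.05 (camera adjusted p = 0.0373; adjusted p = 0.974 with an estimated correlation). Ldha, the lactate dehydrogenase gene, was at 0.16 and the enolase gene Eno2 at 0.51, while Pfkp, a phosphofructokinase gene, was at -0.44. Cytosolic ribosome genes were higher in 19 of 24 members with a median of 0.05 (camera adjusted p = 0.00989; adjusted p = 0.974 with an estimated correlation), for instance Rpl37 at 0.19 and Rps3 at 0.11. Mesenchyme markers were lower in 15 of 18 members with a median of -0.23 (camera adjusted p = 0.00293; adjusted p = 0.974 with an estimated correlation). Among them the collagen gene Col3a1 had 212 ± 111 TPM in WT and 131 ± 47.0 in cKO (SD, n = 5), and Dcn was at -0.53. Endothelial markers were lower in 13 of 14 members with a median of -0.19 (camera adjusted p = 0.00989; adjusted p = 0.974 with an estimated correlation), with Emcn at -0.38 and Eng at -0.31. Erythroid genes were lower in 12 of 16 members with a median of -0.18 (camera adjusted p = 0.00989; adjusted p = 0.974 with an estimated correlation), with Hbb-bt at -0.38 and Hba-a2 at -0.26. The 4 tested Y-linked genes, Ddx3y, Kdm5d, Uty and Eif2s3y, were all lower (camera adjusted p = 0.00233; adjusted p = 0.974 with an estimated correlation). The last difference goes with the sex of the embryos, since Xist exceeded 20 TPM in 1 WT library (WT 3) and in 3 cKO libraries (cKO 1, cKO 3 and cKO 4), and Ddx3y was at 14.8 to 17.6 TPM in the other 6.

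None of these 6 calls held with an estimated correlation or with fry (adjusted p = 0.971 for each), and no single member of any list was called over all genes tested. Single libraries also decided calls made with the preset correlation. The mesenchyme, erythroid and glycolysis calls ended without WT 3 and without cKO 4, both of litter 3, and the sex-linked call without cKO 4. The endothelium, ribosome and glycolysis calls ended without WT 5 or cKO 5, which give the same genotype estimates. The erythroid call also ended without WT 2 or cKO 2, the ribosome call without cKO 2, and the glycolysis call without WT 4 or cKO 3. Processing choices ended calls as well. Quantile normalisation ended the glycolysis and ribosome calls, no litter term or litter as a random effect the ribosome call, array weights the endothelium, glycolysis and ribosome calls, and no filter the erythroid, glycolysis, ribosome and sex-linked calls. Xist as a covariate ended the erythroid, glycolysis and sex-linked calls, leaving out globin and mitochondrial genes the erythroid call, and a replicate block the glycolysis call, with the ribosome call where it had no litter term and the mesenchyme call where it had one. Of 100 splits of the libraries, 78 called at least 6 lists. The globin share of TPM was 4.17% to 5.57% in the 3 libraries of litter 3, of which 2 are WT, and 1.73% to 2.64% in the others.

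**Figure D3:**
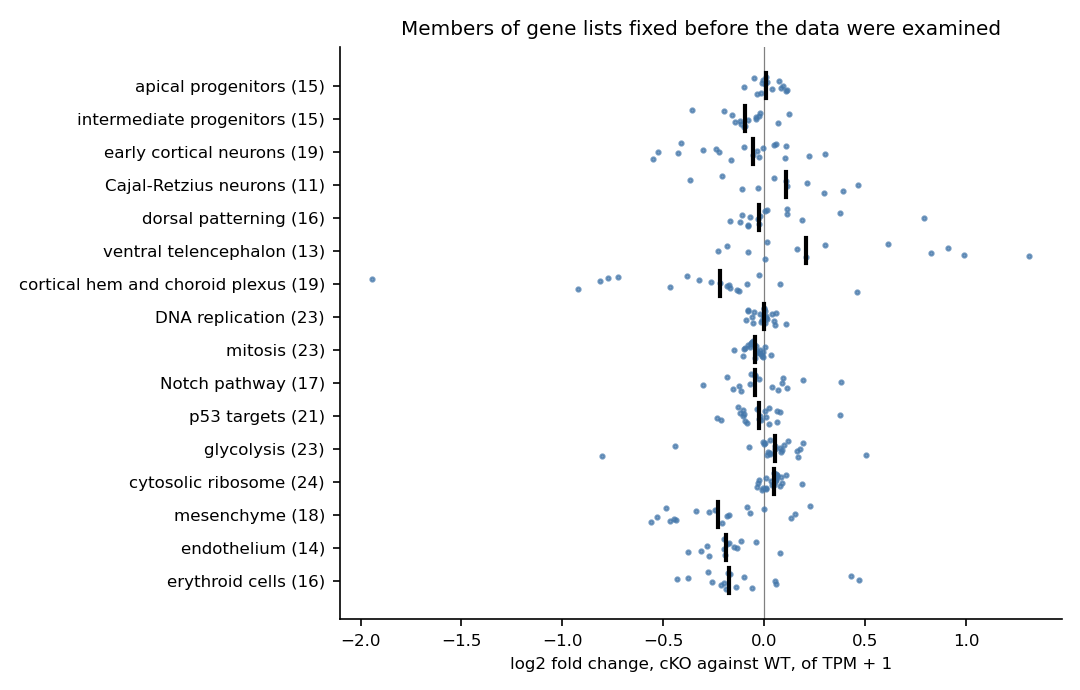
Log2 fold changes of TPM + 1, cKO against WT, for the tested members of 16 gene lists, with 1 point per gene, a black bar at the median and the number of members in brackets. The medians of progenitor, neuron and cell cycle lists lie between -0.09 and 0.11, and those of mesenchyme, endothelium and erythroid cells at -0.23, -0.19 and -0.18.

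The ventral telencephalon list had a median of 0.21, with Six3 at 0.61, and its member Dlx1 ranged from 0.36 to 65.3 TPM among WT and from 0.18 to 33.6 among cKO libraries. The list of cortical hem and choroid plexus had a median of -0.22, with Wnt2b at -0.78, and its member Ttr ranged from 11.3 to 251 TPM among WT and from 0 to 689 among cKO libraries. Diencephalon and eye genes had a median of 0.08, with Barhl2 at 0.47 and Irx3 at 0.27, and surface ectoderm genes of 0.39, with Epcam at 0.44 and Perp at 0.37. Dorsal patterning genes had a median of -0.02, with Fgf15 at 0.79 and Nr2f2 at 0.38. Among 8 pericyte markers, with a median of -0.07, Rgs5 was at -0.18 and Ndufa4l2 rose when adjusted over the list alone (0.54; limma adjusted p = 0.0410), from 6.69 ± 0.757 to 10.3 ± 1.96 TPM, and no other list had such a member. Microglia and macrophage markers had a median of -0.05, with Lyz2 at -0.36 and Fcer1g at 0.18. None of these 7 lists was called (camera adjusted p of 0.0513 or more), and 4 of them were called in alternatives. The ventral list was called with array weights, in litter 1 only and without WT 5, cKO 5 or litter 5. The hem and choroid plexus list was called in the 3 fits without a fixed litter term, with array weights, with Xist as a covariate, in litter 1 only and without WT 4, WT 5, cKO 1, cKO 3, cKO 5 or litter 5. Surface ectoderm was called with no filter, without globin and mitochondrial genes, in litters 3 and 5 only and without WT 1, WT 2, cKO 1 or cKO 2, and microglia and macrophages in the 3 fits without a fixed litter term and without cKO 4 or litter 3.

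The remaining lists were not called either. Signalling targets had medians of -0.09 for Wnt, -0.06 for Hedgehog, -0.10 for NF-kappaB and -0.04 for interferon, with Fzd10 at -0.46 and Bmp4 at 0.46, Cdon at -0.31 and Ptch1 at 0.54, Vcam1 at -0.25 and Bcl2l1 at -0.10, and Stat2 at 0.24 and Ifit2 at -0.08. Stress and handling lists had medians of 0.00 for hypoxia, -0.02 for the unfolded protein response, -0.07 for immediate early genes and 0.01 for heat shock, with Stc2 at -0.20 and Adm at -0.25, Trib3 at -0.31 and Hspa5 at 0.10, Atf3 at -0.38 and Ier3 at -0.25, and Hspe1 at 0.13 and Hspa1b at -0.17. Axon guidance and adhesion genes had a median of -0.10, with Epha7 at -0.34 and Nrp1 at -0.38, and synapse genes of 0.02, with Nrxn2 at 0.27 and Gria2 at -0.22. Medians were 0.02 for cholesterol synthesis, -0.08 for mitochondrial transcripts, -0.07 for the 4 tested clustered protocadherins, 0.00 for other BTB zinc finger genes and -0.04 for chromatin partners, with Fdps at -0.09 and Sc5d at 0.12, mt-Nd3 at -0.12 and mt-Atp8 at -0.29, Pcdhgb1 at -0.26 and Pcdhb7 at -0.11, Zbtb4 at -0.29 and Hic1 at -0.33, and Mbd2 at 0.20 and Mta2 at -0.11. The smallest adjusted p among these 15 lists was 0.0716 (camera, axon guidance). Axon guidance was called with the filter of TPM at least 5, with Xist as a covariate, in litter 1 only, in litters 3 and 5 only and without WT 1, WT 2, cKO 1 or cKO 2. Synapse genes and Wnt targets were called without WT 5, cKO 5 or litter 5 and in litter 1 only, synapse genes also with array weights and in litters 3 and 5 only. Mitochondrial transcripts were called in litter 1 only and without cKO 4 or litter 3, and hypoxia in litters 3 and 5 only. In 10 of the lists that were not called, the median, the mean and the camera direction differed in sign. They are the dorsal patterning, upper-layer, pericyte, DNA replication, Notch, Hedgehog, interferon, hypoxia, heat shock and mitochondrial lists.

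The effect of the genotype was then compared between litters. No gene had a called interaction of genotype with litter 1 against the other litters (limma; smallest unadjusted p = 0.00011, for 2810008D09Rik). Without cKO 4, which leaves litter 3 with WT libraries only, 21 genes were called, and without WT 5 or cKO 5 the number was 3. Litter itself was the larger source of variation. The first principal component held 36.0% of the variance and placed litter 3 (scores of 25.8 to 43.6) and cKO 5 (17.4) apart from litter 1 (-14.8 to -26.0) and WT 5 (-9.38). Between litter 3 and litter 1, 803 genes were higher and 3575 lower in litter 3, and between litter 5 and litter 1 the numbers were 1 and 2 (limma, adjusted p under 0.05).

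**Figure D4:**
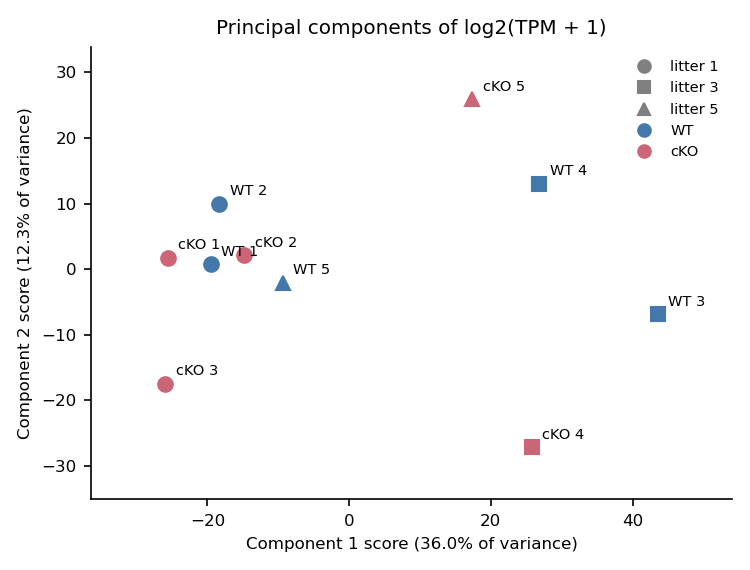
Scores of the 10 libraries on the first 2 principal components of log2(TPM + 1), with colour for genotype, marker shape for litter, and the share of variance on each axis. The libraries of litter 3 lie at 25.8 to 43.6 on the first component and those of litter 1 at -14.8 to -26.0, with both genotypes on each side.

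The authors' deposited table lists 7 genes. The directions of Gm9855 (5.86), Tdg (-1.63), Gm3055 (-1.82) and Gm32687 (-7.29) in the authors' deposited table, on a scale taken as log2, are those of the TPM values. The sizes differ, since the log2 ratio of mean TPM was 3.43 for Gm9855, -0.75 for Tdg and -1.21 for Gm3055, and the source of the gap was not tested. For Gm5806, the Tdg pseudogene, the authors' deposited table gives -3.41 (adjusted p = 7.29e-05), while its TPM was 1.18 ± 0.247 in WT and 2.77 ± 0.310 in cKO, an opposite direction. ENSMUSG00000117667, which matches Tdg over 203 bases, has -5.34 in the authors' deposited table and was not analysed here. Fgf17, which encodes a growth factor of the rostral patterning centre, is higher in the authors' deposited table (3.49, SE 0.76, adjusted p = 0.0178). Its TPM, too low for the filter, was 0.108 ± 0.143 in WT and 1.83 ± 1.61 in cKO (SD, n = 5; exact permutation p = 0.0159, within litters 0.0167). With no filter the log2 fold change of Fgf17 was 1.28 (SE 0.25) and did not pass (limma adjusted p = 0.999).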

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

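The tests of reads shared among Tdg copies, of lower Tdg output and of sequence differences around Zbtb7a were chosen only after the result was seen, and the other tests in this part were set before their results.

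In 4 of 48 groups of 5 libraries 1 library lay far from the others, by the ratio of its gap to the range of the group (critical value 0.71), where chance gives about 1 in 20. The ratio was 0.7169 for Gm10163 in cKO, 0.8418 for AC158605.1 in cKO, 0.7241 for Treml2 in cKO and 0.7143 for Fgf17 in WT.

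Tdg was 40.4% lower in cKO while its processed pseudogene Gm9855 was more than 10-fold higher. Of the 3 copies of Tdg with at least 98% identity over 1193 bases or more, Gm9855 was called higher and Gm5597, listed at 0, lower, while Gm5806 had higher TPM that did not pass (limma adjusted p = 0.615) and is lower in the authors' deposited table (-3.41). The summed TPM of Tdg and its copies was 21.218 higher in cKO, or 8.827% (exact permutation p = 0.167). Reads moved between transcripts of unlike length, 3502 bases for Tdg and 1194 for Gm9855, change this sum, so it cannot test them. The length-weighted sum, which moved reads would keep, was 52.1 lower on the scale of TPM, or 22.5% (exact permutation p = 0.0159). At these lengths this argues against moved reads as the whole source. The lengths behind the TPM values are not known, so neither reads shared among the copies nor lower Tdg output is decided. A candidate source of moved reads is a sequence difference from the reference in the Tdg allele that cKO embryos carry, which needs the reads and was not tested. An effect of Zbtb7a loss on Tdg or on Gm9855 stays open and untested.

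Of the 5 called genes, 3 lie within 2 Mb of Zbtb7a, the locus that carries the floxed allele. With Zbtb7a and the called genes left out, the odds ratio of an unadjusted p under 0.05 in the window against elsewhere was 2.2448 (95% interval 0.801 to 5.09, Fisher's exact test p = 0.0601), so sequence differences carried on the floxed chromosome may contribute but are not decided. Of the window genes with a near-identical copy 5 of 11 had such a p, and of those without one 4 of 113 (odds ratio 1.5689, 95% interval 0.417 to 4.17, one-sided Fisher's exact test p = 0.261), so reads shared between copies as the only source cannot be excluded. Zfp433, the 99.9% identical copy of Gm32687, differed by 0.096 TPM while Gm32687 went from 5.10 TPM to a listed 0. Their sum fell from 11.7 ± 1.46 TPM in WT to 6.68 ± 0.898 in cKO (exact permutation p = 0.00794), so the fall of Gm32687 had no matching rise in Zfp433. The copies of Gm3055, Zfp781 and BC024063, were higher in cKO, and the sum of these 3 was 16.6 ± 2.22 TPM in WT and 13.8 ± 0.678 in cKO (exact permutation p = 0.0397). Every cKO embryo carries both the floxed chromosome and the deletion, so linked sequence and loss of Zbtb7a cannot be told apart in this window.

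Fgf17 was higher in cKO in the authors' deposited table and in TPM, with 4.24 TPM in cKO 5, 2.64 in cKO 4 and at most 0.35 in any WT library. The genotypes overlapped, since cKO 1 had 0.25 TPM and WT 5 had 0.35. Over the 10 libraries Fgf17 and the mean of the ventral telencephalon list had a Spearman rho of 0.2979 (permutation p = 0.396, adjusted over 2 relations 0.396) and a Pearson r of 0.14 (permutation p = 0.699, adjusted 0.699), or 0.79 without the 2 farthest libraries. Fgf17 and Fgf8 had a rho of 0.3761 (permutation p = 0.283, adjusted 0.396) and an r of 0.61 (permutation p = 0.0509, adjusted 0.102), or -0.26 without the 2 farthest, so the r rests on those libraries. Neither ventral nor rostral tissue in the dissections was decided, with too few libraries per genotype or litter for values within them. The library with the highest Fgf17, cKO 5, had 0.18 TPM of the ventral gene Dlx1 and the highest Fgf8, 2.15 TPM. The next in Fgf17, cKO 4, had 29.9 TPM of Dlx1 and 0 of Fgf8. An effect of Zbtb7a loss on Fgf17 stays open and untested.

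The counts of calls were set against 100 of the 126 splits of the libraries into 5 and 5, the real one included, of which 1 cannot be fitted with a litter term. A split and its mirror are 1, so each other split was counted by the larger of its 2 directions, against each real count. At least as many as the 1 gene higher were called in 13 splits, with 15 as the highest of the others. Chance therefore cannot be excluded for that count. The count takes no account of the size or p-value of the change of Gm9855, the gene behind it. At least as many as the 4 genes lower were called in 3 splits, with 15 as the highest of the others. This is under 0.05 for that count taken alone, with no adjustment over the 3 counts compared here. Without that adjustment chance is not excluded for it. The number of genes lower also fell to 2 when some single libraries were left out. Those fits hold fewer libraries, so this fall does not bear on chance. As many lists (6) were called in 78 splits, with 16 as the highest of the others, so chance cannot be excluded for the lists. Of the 60 splits within litters, 8 reached the count of genes higher, 2 that of genes lower and 53 that of lists. The real split is among them in each case. The split with the most genes called 16, led by genes of the ventral telencephalon. It was picked for its count, so that number is no test of a structure of the samples.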

How the results depend on the processing

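Leaving out litter 3 or litter 5 was chosen after seeing the data, and the other alternatives were planned. Gm9855 was the gene called higher in every one of the 30 alternatives for that count, and Zbtb7a stayed lower in all of its alternatives, from -0.67 (litters 3 and 5 only) to -1.29 (litter 1 only) on the log2 scale, called only without cKO 4. Over 19 named genes and 542 values under alternatives, 506 kept their direction and side of the threshold, 36 lost the call and 0 reversed. Only the 5 called genes could lose a call. The 506 include all values of the other named genes, which stayed uncalled, so they do not measure how stable the calls are. Genes that a filter left out have no value there. Gm32687 lost its call in litter 1 only and in litters 3 and 5 only, and Tdg in these and with a replicate block without litter. Gm3055 and Gm5597 lost theirs in many alternatives. Of 4137 values of 144 list members, none of them called, 155 changed sign.

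The 4 genes lower in cKO became 2 with a filter of TPM at least 5, 2 with Xist as a covariate, 0 in litter 1 only, 2 in litters 3 and 5 only, neither of them among the 4, and 2 without litter 5. Leaving out 1 library gave 2 to 4, with 2 without WT 2, WT 3, cKO 1 or cKO 3. It was also 2 without WT 5 or cKO 5, which repeat the genotype estimates without litter 5. The 2 lower in litters 3 and 5 only were Gm13841 and Gm8210, and the 4 without cKO 4 included Zbtb7a. The 6 lists called became 3 with no filter on low values, 11 in litter 1 only, 11 in litters 3 and 5 only, 10 without litter 5, 0 with an estimated correlation in camera and 0 with fry. Leaving out 1 library gave 5 to 11 lists, with 10 without WT 5 or cKO 5 and 11 without cKO 1. Interaction calls were 1 with no filter, 21 without litter 3 and 3 without litter 5, against 0 in the main test, and 0 to 21 without 1 library. Zbtb7a ranged from -1.27 to -0.89 without 1 library. The smaller sets hold fewer libraries and the stricter filter fewer genes. In the other cases the cause was not tested.

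The animal numbers do not pair the libraries. The correlations of the deviations of same-numbered libraries were 0.27, 0.08, -0.29, 0.30 and -0.17, and not every library correlated best with its own number. With the number as a replicate block 1 gene was lower without a litter term and 2 with it, and 1 was higher in both. Whole reads could not be recovered from TPM, so the count test was not run. The unknown depth leaves the counting error of genes with low TPM, such as Fgf17 and Gm5597, unmeasured.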

Other observations

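The comparison of litters in gene lists and the look at a regrouping of the libraries were chosen after the data were seen.

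Litter 3 differed from litter 1 in its tissue profile, in a fit that averages over the genotypes. The median of all tested genes was shifted by -0.16 on the log2 scale, and the list medians lie beside that shift. Of 16 erythroid genes 15 were called higher in litter 3 with a median of 1.34 (camera adjusted p = 1.81e-18; adjusted p = 0.0541 with an estimated correlation), for instance the embryonic globin genes Hbb-y at 1.40 and Hba-x at 1.75 and the haem synthesis gene Alas2 at 1.39. Mesenchyme markers were called higher in 12 of 18 members and lower in 1, with a median of 0.88 (camera adjusted p = 6.43e-09; adjusted p = 0.513 with an estimated correlation), with Lum at 1.15, Foxc1 at 0.94 and Col3a1 at 0.95. Cytosolic ribosome genes were called higher in 14 of 24 members with a median of 0.22 (camera adjusted p = 6.48e-12; adjusted p = 0.513 with an estimated correlation), with Rps14 at 0.52, and microglia and macrophage markers in 3 of 15 with a median of 0.38 (camera adjusted p = 3.31e-05; adjusted p = 0.513 with an estimated correlation). Neuronal, progenitor and cell cycle genes were lower. Early cortical neuron markers were called lower in 14 of 19 members with a median of -1.02 (camera adjusted p = 0.000109; adjusted p = 0.513 with an estimated correlation), among them Nhlh1 at -1.04, Neurod2 at -1.78 and Bcl11b at -1.29. Intermediate progenitor markers were called lower in 12 of 15 with a median of -0.93 (camera adjusted p = 3.31e-05; adjusted p = 0.513 with an estimated correlation), with Eomes at -1.27 and Neurog2 at -1.03. Apical progenitor markers were called lower in 11 of 15 with a median of -0.50 (camera adjusted p = 0.0028; adjusted p = 0.513 with an estimated correlation), with Sox2 at -0.65. Called lower were also 17 of 23 mitosis genes, 15 of 23 DNA replication genes and 14 of 17 chromatin partners, with medians of -0.42, -0.42 and -0.51 (camera adjusted p = 0.000791, 0.00195 and 7.82e-05; adjusted p = 0.513 with an estimated correlation for each). These 10 directions held under median-of-ratios scaling, quantile normalisation and without globin and mitochondrial genes, but the sizes did not. The median ranged from 0.10 to 0.41 for ribosome genes, from -0.42 to -0.22 for DNA replication, from -0.42 to -0.23 for mitosis, from -0.51 to -0.33 for chromatin partners and from -0.50 to -0.31 for apical progenitors. The camera test with the preset correlation also called 6 further lists, endothelium, hem and choroid plexus and surface ectoderm higher and synapse, axon guidance and BTB zinc finger genes lower. None of these 6 was called with an estimated correlation (camera adjusted p of 0.513 or more). Litter 5 against litter 1 had 12 lists called with the preset correlation and none with an estimated one (camera adjusted p of 0.228 or more). Of these 12, 10 were called in the same direction in litter 3, such as ribosome genes (median 0.19), erythroid genes (0.47), chromatin partners (-0.27), mitosis (-0.28) and early cortical neurons (-0.55). Both litters were compared with the same litter 1 libraries. Shared directions therefore cannot tell a trait of litters 3 and 5 from one of litter 1. As lists, heat shock and mitochondrial genes were called lower in litter 5 and not in litter 3, and mesenchyme was not called in litter 5. Single heat shock genes were called lower in litter 3 as well, 6 of 10 with a list median of -0.29, while 1, Hspe1 at 0.37, was called higher. In litter 5 the genes called lower were 2 of 10 with a median of -0.31. Litter 3 holds 2 WT libraries and 1 cKO library, and its 3 embryos also had the highest globin shares.

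Ventral telencephalic genes varied from embryo to embryo. Dlx1, a homeobox gene of the ganglionic eminences, had 65.3 TPM in WT 5, 33.6 in cKO 2, 30.8 in cKO 3, 29.9 in cKO 4 and 13.6 in WT 3, and 3.62 TPM or less in the other 5 libraries. Gad2, a gene of GABA synthesis, had 2.51 to 10.4 TPM in those 5 libraries and 0.46 or less in the others. The split of the libraries that separates them called 16 genes, led by Dlx5, Gsx2, Dlx2 and Dlx1. It was the split with the most calls of those drawn, so its count cannot be set against that of the genotypes. None of the 16 is on chromosome X or Y.

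The Rpl21 pseudogenes Gm10240 and Gm13370 each match Gm10163 at 100% over all 481 bases of its transcript. They had the same mean TPM, 255 in WT and 310 in cKO, while Gm10163 had a log2 fold change of -4.30 that did not pass.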
